A study of Oryza sativa with 51 samples.

How the data were processed

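Leaves of field-grown rice (cultivar Koshihikari) were measured on a custom Agilent oligonucleotide array, with the labelled RNA of 1 sample in each dye channel. The 51 samples form 4 one-day courses with a sample every 2 h, named here by the days from transplanting to sampling on the first day: DAT35 (13 samples), DAT21 (13), DAT58 (12, with no 04:00 sample) and DAT44 (13). The 51 samples lay on 26 arrays, 25 of which held a sample in both channels. The remaining array had 1 channel that belonged to no sample of the series, and this channel was not used.

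The deposited files hold intensity values of 156732 spots per array from Agilent Feature Extraction 10.5.1.1, per the file headers. Its processed signal was background-subtracted, spatially detrended and dye-normalized within the array, per the file headers. The submitters' processing notes also name the affy package, with no version or role. The analysis started from this processed signal in each sample's own channel (red for Cy5, green for Cy3), because it is already corrected for background. The mean and background intensity, which are deposited per channel as well, served an alternative only.

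Control spots (4854) were left out, log2 processed signals of the 151878 probe spots were quantile normalised over the 51 channels with limma 3.58.1 in R 4.3.3, and spots with the same 60-base sequence were averaged. This gave 148841 unique probe sequences. A sequence was tested if it was well above background (Feature Extraction's flag) in at least 12 of the 51 channels and had no outlier flag in any, which removed 219 sequences for the outlier flags and left 95750. Of the tested probes 69879 were well above background in all channels, while 32903 sequences on the array were so in none. No spot was saturated. Values near background are replaced by small positive ones in the processed signal, so a fitted fold against such values is no measure of size. Where a probe was not well above background in any sample of the lower side, the fold is given as a lower bound. It sets the mean of the brighter samples against the mean of the higher of each channel's lowest well-above-background signal and the dim probe's own signal.

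The files pair probe names and sequences with no gene or locus, and no genome was used here. The unit of the tests was therefore the probe sequence, 29 gene lists fixed beforehand found no members and were not tested, and several probes can report on 1 transcript. To show how far this matters, probes that share 25 bases were joined into 62405 groups among the tested probes. The rule for named genes, which asked for a locus and a description, could be applied only by its ranking. At most 2 probes rising and 2 falling were named per comparison, those with the largest fitted change among the probes called (for the rhythm, 2 that peak by day and 2 by night; for the interaction and the rhythm differences, the 2 with the smallest p), each from another group of overlapping probes.

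Comparisons were fitted with limma's lmFit and eBayes with the array as a random block (correlation of channels on an array 0.29 to 0.44 over the models, each estimated on 5000 probes drawn with seed 1). Dye was a covariate in every model. The rhythm was tested with the cosine and sine of a 24 h cycle of clock time beside series. Levels were compared between series with the 12 clock hours as a block. Rhythm differences were tested as products of cosine and sine with sampling date and with transplanting date. The 08:00 samples of consecutive mornings were compared in a model with all 13 time points. Probes with a Benjamini-Hochberg adjusted p under 0.05 are said to be called, and counts at 2-fold or more are given beside them. The tests, the covariates, the first set of alternatives and the ranking for named probes were chosen before the data were examined. The probe sequence as the unit was not part of that plan. Nor were the smaller number of named probes, their split by day and night and the choice from different groups of overlapping probes.

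Samples at 1 clock time were checked for deviating together. Over 75 pairs of samples from different series at the same time point the correlation of their deviations from the series means was 0.5 or more, with a median of 0.745, so the time points pair the series and clock hour stayed in the model. Slide and scan day were read from the files as batches. The arrays came from 8 slides, 3 of which held samples of more than 1 series, and 1 sample was scanned on another day than the rest. Slide was added as a fixed and as a random block. Within the slides that hold more than 1 series too few samples shared a clock time to give a value.

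The models of the main comparisons were tested on simulated data made from the real probe means, spreads and array correlations, with 200 changed probes per comparison. The simulated data held no slide effect and no floor for dim values, and the other calculations were not simulated. For a simulated change of 2 on the log2 scale, 95.5% of the changed probes were recovered for the rhythm, 100% for the sampling date and the transplanting date, 92.4% for the interaction, 66.7% for rhythm differences between sampling dates, 71.2% for those between transplanting dates and 97% for the second morning, each in a step that ran on 95750 probes. For a change of 0.5, recovery was 49.3% for the rhythm, 70.1% for the sampling date, 76.1% for the transplanting date, 23.9% for the interaction, 5.97% and 11.9% for the rhythm differences, and 29.9% for the second morning.

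Alternatives covered the background correction (normexp, offset 50), the scaling (each channel's 75th percentile, or loess and Aquantile), the filter on dim probes, the array, dye and slide terms, the clock hour block, the moderation of the variance, the shape of the daily curve and the samples included. The alternatives that leave out the samples of slide 1, the sample scanned on another day, the 3 DAT21 samples least like the others, the samples at 20:00 or those at 08:00 and 20:00, and the one that keeps 1 probe per group of overlapping probes, were added after the data were seen. Means over the probes of a locus and gene list tests were not run, because no locus was known. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.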

Results

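Gene expression was measured in leaves of rice (Koshihikari, a paddy cultivar) over complete days in a field at Fukuyama, Japan. Plants transplanted on 3 June or on 17 June were sampled at the same clock times, every 2 h from 08:00 to 08:00 of the following morning. On 8 July the plants were 35 (DAT35, 13 samples) or 21 days after transplanting (DAT21, 13 samples). On 31 July they were 58 (DAT58, 12 samples) or 44 days after transplanting (DAT44, 13 samples). Between 54% and 63.4% of the probes were well above background in a sample, with a median of 61.2%, and the median processed signal ranged from 35.1 to 87.7. There was 1 sample per time point and no replicate, each date was 1 day in 1 field, and the number of arrays limits the precision. The p-values therefore measure only the spread among time points around the fitted models, and the weather and light of the days were not analysed here.

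The first question was which transcripts follow the time of day in the field. Of 95750 probes tested, 87310 (91.2%) followed a 24 h cycle common to the 4 series, and 51747 (54%) did so with a fitted change of at least 2-fold between trough and peak. The median change of the rhythmic probes was 2.31-fold, while 21931 probes changed by 4-fold or more and 4099 by 16-fold or more. Peaks gathered in the early morning and in the late afternoon. Among the probes with a change of at least 2-fold, 6112 (11.8%) peaked from 06:00 to 08:00 and 6729 (13%) from 16:00 to 18:00, with the fewest, 2484 (4.8%), from 12:00 to 14:00.

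**Figure D1:**
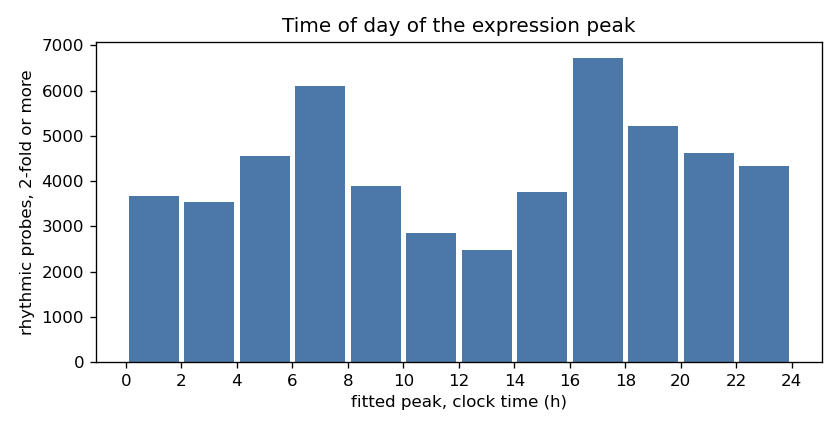
Number of rhythmic probes with a fitted change of at least 2-fold (vertical axis, bars) by the clock time of their fitted peak in 2 h classes (horizontal axis, h), over the 4 series together. The classes from 06:00 to 08:00 (6112 probes) and from 16:00 to 18:00 (6729) stand above their neighbours, and that from 12:00 to 14:00 (2484) is the lowest.

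The largest daily changes ran between values not well above background and some of the brightest on the array. Probe eAry2_29702 (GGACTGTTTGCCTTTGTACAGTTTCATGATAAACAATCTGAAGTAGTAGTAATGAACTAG) had a log2 signal of 14.46 ± 0.16 (SD, n = 4 series) at 16:00 and was not well above background in any series at 06:00, at least 3070-fold lower. Probe 44kb3_33571 (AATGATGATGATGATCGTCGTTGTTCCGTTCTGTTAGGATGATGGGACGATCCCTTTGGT) stood at 14.03 ± 0.15 at 16:00 and was at least 2600-fold lower at 02:00. By night, eAry2_28990 (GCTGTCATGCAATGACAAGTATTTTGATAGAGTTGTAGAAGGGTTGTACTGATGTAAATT) reached 15.04 ± 0.14 at 02:00 and was at least 4430-fold lower at 12:00. Probe 44kb3_41367 (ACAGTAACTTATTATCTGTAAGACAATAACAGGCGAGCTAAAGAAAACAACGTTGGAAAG) reached 14.50 ± 0.18 at 02:00 and was at least 3040-fold lower at 12:00. Their adjusted p in limma's F test were 1.77e-19, 5.65e-18, 4.97e-24 and 4.03e-24, and each had its fitted peak within the afternoon or around midnight in 4 of 4 series. After normexp their fitted log2 changes from trough to peak were smaller (9.341, 8.675, 10.49 and 9.859, against 13.82, 13.4, 13.24 and 13.06). Fitted alone, the series had 73810 (DAT21), 65246 (DAT35), 77818 (DAT44) and 72931 (DAT58) rhythmic probes, and 50232 probes (52.5%) were rhythmic in all 4. With 1 probe kept from each of the 62405 groups of overlapping probes, 56648 were rhythmic.

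**Figure D2:**
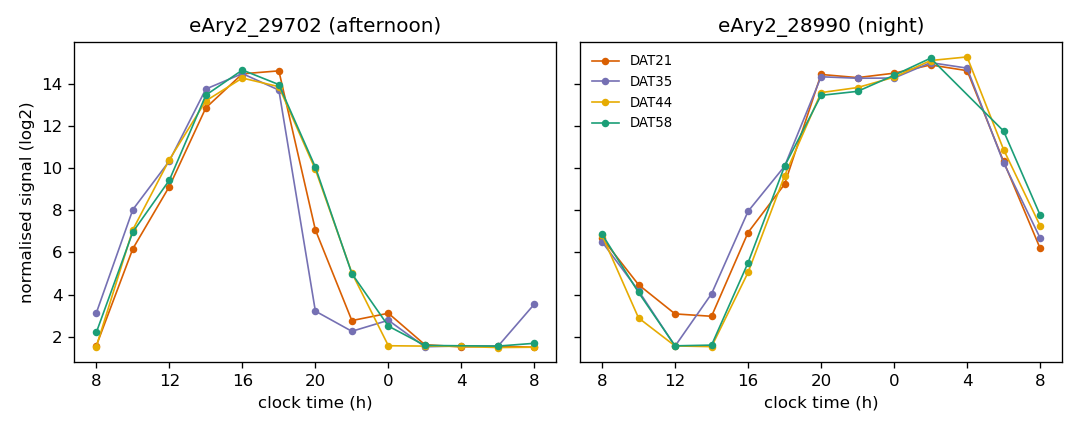
Normalised log2 signal (vertical axis) of eAry2_29702 (left) and eAry2_28990 (right) against clock time (horizontal axis, h), 1 point per sample and 1 line per series. The left probe peaks at 16:00 (mean 14.46) and the right one at 02:00 (mean 15.04) in the means of the 4 series.

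The comparison of 31 July with 8 July asked how leaf expression differs between dates in the growing season. It joins calendar date, the age of the plants and the days' weather. In mean level 52690 probes (55%) differed: 30434 were higher on 31 July and 22256 lower (26657 and 26087 with each channel scaled to its 75th percentile), of which 3120 and 4024 by 2-fold or more (989 and 1775 after normexp background correction, 973 and 1752 among probes well above background in all channels). Probes with a peak in the evening were more often higher than lower at the later date, and those with a peak in the morning more often lower. Of the rhythmic probes with a change of at least 2-fold, 40.9% of those peaking from 20:00 to 22:00 were higher on 31 July and 16% lower, while from 06:00 to 08:00 16.8% were higher and 39.5% lower. Probe 44kb3_29036 (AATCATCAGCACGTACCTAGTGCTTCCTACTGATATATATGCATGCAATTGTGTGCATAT) was not well above background in any of the 26 samples of 8 July and was so in 25 of 25 of 31 July, at least 136-fold higher by the bound (adjusted p = 1.7e-32 in limma). Probe 44kb3_10988 (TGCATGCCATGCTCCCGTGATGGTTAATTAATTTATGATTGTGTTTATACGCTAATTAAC) behaved alike, at least 168-fold higher (adjusted p = 2.69e-28 in limma). After normexp, with an offset of 50, the changes of the 2 probes were smaller, 4.857 and 4.942 on the log2 scale.

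A pair of named probes went the other way. Probe eAry2_12888 (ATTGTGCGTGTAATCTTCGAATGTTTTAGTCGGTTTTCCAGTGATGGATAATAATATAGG) fell by 7.12 ± 0.36 (SE) on the log2 scale (-4.515 after normexp background correction; adjusted p = 2.74e-18 in limma), from means of 10.59 in DAT21 and 9.96 in DAT35 to 3.35 in DAT44 and 2.79 in DAT58, where 10 of 25 samples were well above background. Probe eAry1_26569 (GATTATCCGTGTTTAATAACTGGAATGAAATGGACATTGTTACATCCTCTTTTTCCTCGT) fell by 6.74 ± 0.63 (-4.782 after normexp; adjusted p = 3.72e-11 in limma), with 14 of 25 samples of 31 July well above background. Tested within each transplanting, 28388 probes differed between DAT58 and DAT35 and 53329 between DAT44 and DAT21. With slide as a fixed block these counts were 4518 and 8480, and without the clock hour block 4483 and 20713. Both comparisons called 20518 probes, against 15811 expected for independent lists, and 95% of the 20518 went in the same direction. The correlation of the 2 sets of log2 changes was 0.69 over probes, which are not independent replicates. The pairs of series share no sample, but they share the days, the field, some slides and some arrays, so neither is an independent repeat of the other. With slide as a fixed block 5064 probes were higher and 3229 lower and eAry1_26569 was no longer called (a change of -6.203, and of -4.348 for eAry2_12888), where each slide held samples of 1 or 2 series only.

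The difference between dates was uneven over the day. Each time point's difference was tested against the mean difference over the 13 time points, so a difference shared by all of them is not counted. It departed from that mean in 36915 probes at the first 08:00, 28484 at 20:00 and 14910 at the second 08:00, but in 495 at 02:00. At 20:00 the changes between dates in the 2 transplantings correlated at 0.784 over probes, the highest of the time points that had a sample of each series.

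**Figure D3:**
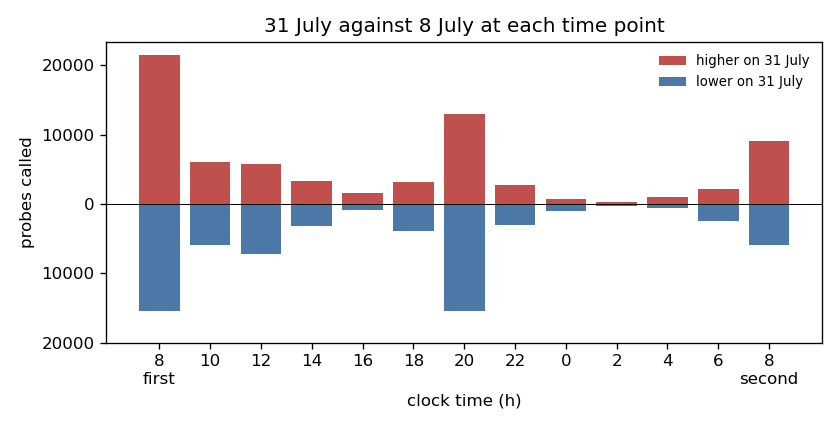
Number of probes whose difference of 31 July minus 8 July departed from its mean over the 13 time points (vertical axis, limma, adjusted p under 0.05). Bars above 0, labelled higher, count differences above that mean, and bars below 0, labelled lower, those below it. The horizontal axis gives clock time in h, with the 08:00 samples marked as first and second morning. The first 08:00 (36915 probes) and 20:00 (28484) stand out and 02:00 has the fewest (495).

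Plants of the later transplanting were compared with those of the earlier one to ask what a difference of plant age within 1 day does. Averaged over the dates, 5392 probes were higher and 6941 lower after later transplanting, of which 629 and 244 by 2-fold or more (143 and 76 after normexp background correction, 117 and 49 among probes well above background in all channels, 451 and 680 with slide as a fixed block). Probe 44kb3_13258 (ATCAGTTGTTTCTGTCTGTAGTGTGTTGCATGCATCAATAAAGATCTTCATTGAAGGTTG) was higher by 3.90 ± 0.79 (SE) on the log2 scale (adjusted p = 0.000956 in limma), with series means from 11.18 in DAT21 to 2.74 in DAT58. Probe eAry2_47741 (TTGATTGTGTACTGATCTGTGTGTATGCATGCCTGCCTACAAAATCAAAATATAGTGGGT) was higher by 3.02 ± 0.52 (adjusted p = 0.000168 in limma), from a difference on 8 July, since no sample of 31 July was well above background. Probe Cuffnpc_00332 (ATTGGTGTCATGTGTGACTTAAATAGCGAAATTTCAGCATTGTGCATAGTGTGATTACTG) fell by 3.72 ± 0.17 (adjusted p = 1.4e-17 in limma) and 44kb3_23620 (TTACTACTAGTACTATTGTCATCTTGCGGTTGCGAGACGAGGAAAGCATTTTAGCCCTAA) fell by 3.49 ± 0.23 (adjusted p = 4.29e-13 in limma) after later transplanting. After normexp the 4 changes were 2.633, 1.868, -2.282 and -2.244. The 2 falling probes were well above background in 1 of 13 samples of DAT21, and eAry2_47741 in 3 of 13 of DAT35. Probe 44kb3_13258 was so in 9 of 13 samples of DAT35 and in 3 of 12 of DAT58. On 31 July alone it was not called (DAT44 minus DAT58 2.989, adjusted p = 0.219 in limma). Dim samples thus leave open the sizes of the changes of all 4 probes. A fixed slide block left 1052 probes higher and 2204 lower, 44kb3_13258 (a change of 1.486) and eAry2_47741 (2.556) no longer among them, and a random one 3260 and 4256. The balance of directions turned with the scaling, from 43.7% of the called probes higher to 54.3% with each channel scaled to its 75th percentile.

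Whether the effect of transplanting differed between the dates was tested as an interaction, which called 22562 probes (12751 above 0 and 9811 below). In 20114 of these (89.1%) the difference between transplantings was larger on 8 July, with a median size of 0.454 on the log2 scale against 0.141 on 31 July. On 8 July 13924 probes were higher and 18988 lower in DAT21 than in DAT35, and on 31 July 607 were higher and 674 lower in DAT44 than in DAT58. With slide as a random block 18028 probes differed on 8 July and 562 on 31 July, and with a fixed one 5319 and 322. Without the 08:00 and 20:00 samples these counts were 27035 and 400. Probe Cuffnpc_00332 was called for the interaction (adjusted p = 2.81e-12 in limma) with a positive value whose size dim samples leave open (5.207 on the log2 scale, 2.329 after normexp), with means of 2.28 in DAT21, where 1 of 13 samples was well above background, 8.75 in DAT35, 13.02 in DAT44 and 14.15 in DAT58. Probe 44kb3_15403 (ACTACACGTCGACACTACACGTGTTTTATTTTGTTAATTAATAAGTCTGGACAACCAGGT) had a negative one, of a size left open alike (-5.29, and -2.252 after normexp; adjusted p = 2.81e-12 in limma), being well above background in 13 of 13 samples of DAT21, in 1 of 13 of DAT35 and in none of 31 July. For transplanting 511 probes were called on both dates, against 440.3 for independent lists, and 184 of the 511 went in the same direction. The interaction called 1172 probes with slide as a fixed block, 5745 with slide as a random block and 14103 without the 08:00 and 20:00 samples.

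**Figure D4:**
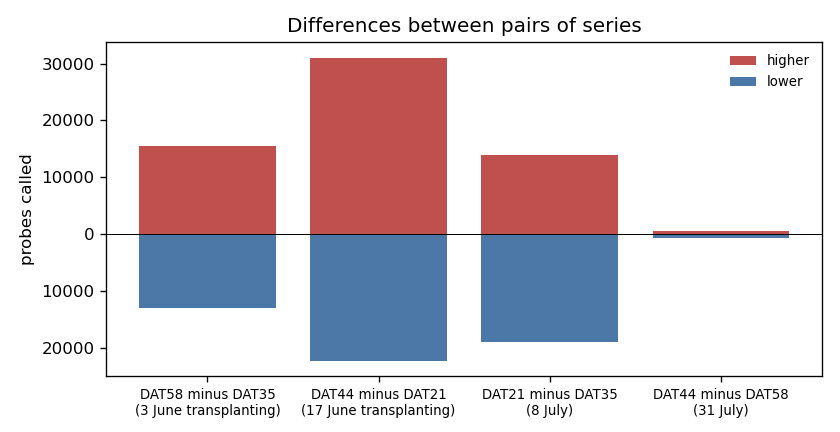
Number of probes called higher (above 0) or lower (below 0) in 4 comparisons of series (vertical axis; limma, adjusted p under 0.05). DAT44 and DAT58 differ in 1281 probes, and DAT21 and DAT35 in 32912.

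**Figure D5:**
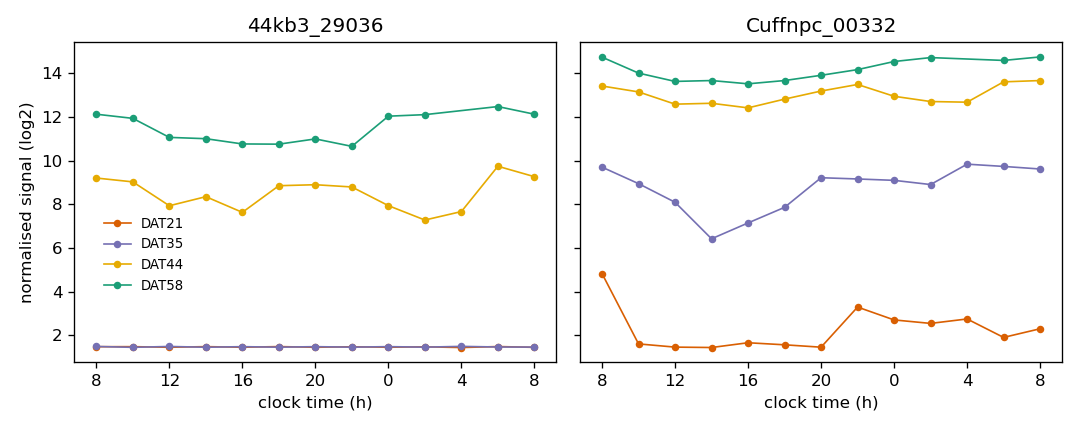
Normalised log2 signal (vertical axis) of 44kb3_29036 (left) and Cuffnpc_00332 (right) against clock time (horizontal axis, h), 1 point per sample and 1 line per series. The left probe is well above background only on 31 July (means 8.51 in DAT44 and 11.50 in DAT58), and the right one has series means of 2.28, 8.75, 13.02 and 14.15 in DAT21, DAT35, DAT44 and DAT58.

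The daily cycle itself also differed between the dates. Peak time or size differed for 11628 probes, 6100 with a larger and 5528 with a smaller change over the day on 31 July. Of the 5282 of these that had a change of at least 2-fold on both dates, 3821 peaked later on 31 July and 1461 earlier, with a median shift of 1.28 h. Over all 21931 probes with a common change of 4-fold or more the median shift was 0.471 h later (jackknife SE 0.213 h over clock hours). With 1 clock hour left out it was 0.302 to 0.557 h. With the series fitted alone it was 0.283 h from DAT35 to DAT58 and 0.65 h from DAT21 to DAT44. Between series of the same date the median shift was 0.328 h from DAT58 to DAT44 and 0.0223 h from DAT35 to DAT21. Probe eAry2_33037 (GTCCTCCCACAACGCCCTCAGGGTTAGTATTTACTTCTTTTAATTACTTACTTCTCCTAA) changed by 0.63 from trough to peak on 8 July and by 3.41 on 31 July on the log2 scale, with peaks at 8.18 h and 9.51 h. Probe 44kb3_5229 (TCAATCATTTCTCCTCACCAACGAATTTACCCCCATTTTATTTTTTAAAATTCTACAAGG) changed by 0.71 and 3.82 (both with an adjusted p of 3.68e-09 in limma). With slide as a fixed block the count was 4730, and with a 12 h harmonic beside the 24 h one it was 21167.

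No difference of the daily cycle between transplantings was detectable. Limma called 0 probes, and 4235 had an unadjusted p under 0.05, where 4787.5 are expected by chance. The smallest adjusted p was 0.0689. Simulated differences of 2 on the log2 scale were recovered in 71.2% of cases, those of 1 in 41.8% and those of 0.5 in 11.9%. Differences of 1 or less therefore stay open, and some of 2 could be missed.

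The 08:00 time point was the only one sampled on consecutive mornings, which shows how far 1 day stands for another. From 8 July to the next morning 28844 probes differed (13777 higher and 15067 lower on the second morning). This count rests on 1 sample per series and morning, and the mornings of a series lay on different slides. The alternatives were run only for the average over the series, whose counts fell strongly in several of them (below). From 31 July 1 probe differed, with 4072 at an unadjusted p under 0.05. The difference between these changes was called for 13770 probes. Averaged over the 4 series as planned, 1621 probes were higher and 3751 lower on the second morning, while the changes of the 2 dates correlated at -0.21 over probes. Of the rhythmic probes with a change of at least 2-fold, 17.9% of those peaking from 16:00 to 18:00 were lower on the second morning in this average, against 0.262% of those peaking from 06:00 to 08:00.

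Probes eAry1_15006 (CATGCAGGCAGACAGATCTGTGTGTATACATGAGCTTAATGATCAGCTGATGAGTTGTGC) and 44kb3_10974 (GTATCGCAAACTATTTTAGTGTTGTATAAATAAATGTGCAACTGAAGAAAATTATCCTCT) were higher on the second morning by 3.46 ± 0.80 and 3.06 ± 0.70 (SE, log2 scale), each in 3 of 4 series (adjusted p = 0.0174 and 0.0161 in limma), and by 1.745 and 1.258 after normexp, with 2 of 4 first-morning samples well above background, while with loess and Aquantile beside normexp eAry1_15006 was not called (a change of 1.605). Probe eAry1_09652 (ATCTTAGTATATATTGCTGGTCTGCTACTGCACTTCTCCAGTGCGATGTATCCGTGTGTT) stood at 11.51 in DAT21 and 8.163 in DAT35 at the first 08:00 and was not well above background in any second-morning sample or any sample of 31 July, at least 8.26-fold lower in the means of the 4 series by the bound (a log2 change of -2.262 after normexp; adjusted p = 0.0209 in limma). Probe eAry1_33540 (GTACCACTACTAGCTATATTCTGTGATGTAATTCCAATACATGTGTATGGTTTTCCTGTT) fell as well (adjusted p = 0.0281 in limma), by a size left open (-3.809, and -2.459 after normexp), since 1 of the 4 second-morning samples was well above background, and it was not called with slide as a random block (-3.452). The average over the series rested on the 8 July series, since limma called 0 probes without DAT21, 0 without DAT35 and 0 without the 3 DAT21 samples least like the others (6935, 7816 and 7273 at an unadjusted p under 0.05). With slide as a fixed block 6 probes were higher and 58 lower, and without the 4 samples of the slide that held the first DAT35 samples 22 and 85, and none of the 4 named probes was called in any of these alternatives, without the array block or with only the 8 samples at 08:00, while their changes were 2.278, 1.497, -2.08 and -1.614 without DAT21, 2.329, 2.261, -3.211 and -3.555 without DAT35, 2.371, 1.383, -2.007 and -1.63 without the 3 DAT21 samples, 4.877, 2.757, -5.408 and -5.081 with the slide block, 2.874, 2.777, -3.913 and -3.806 without slide 1, and 3.212, 2.907, -3.68 and -3.299 in each of the last 2.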

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

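The tests of slide and of swapped labels for the 20:00 samples, of slide for the transplanting difference and of the single pairs of series were chosen only after the results were seen.

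The effect of transplanting differed between dates in 22562 probes by the interaction test. Reassigning the interaction labels within time points gave 1 probe as the highest of the other counts in 100 assignments. An offset of a whole series largely cancels in such mixed assignments, so they cannot exclude chance differences between the series. The same holds for the pairs of series, where the real assignment was the highest in each: 32912 probes against at most 15828 for DAT21 and DAT35, and 1281 against at most 1063 for DAT44 and DAT58.

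That the transplanting difference is large on 8 July and small on 31 July may be a matter of plant age, which the design leaves untested: DAT21 and DAT35 are younger than DAT44 and DAT58. Against a GC trend of the probes stands that 30312 probes differed between DAT21 and DAT35 after each sample's trend on GC content was removed, and 32912 before. Against the 3 DAT21 samples that correlate least with the others (those of both 08:00 time points and of 06:00) stands that 22264 probes differed without them. Slide stays open as a cause, since every slide held 1 or 2 series. The differences between DAT21 and DAT35 at time points on other slides correlated at 0.498 over probes, but with the signs of time points flipped the correlation reached 0.503.

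The daily cycle differed between dates in 11628 probes by the test of the cosine and sine terms by date. In 100 assignments of the samples of a time point to dates the highest other count was 0. A daily curve particular to a whole series is broken up in such mixed assignments. They therefore argue against a chance assignment of single samples, but cannot exclude chance differences between the days or the series.

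In the evening, setting each sample against the daily profile of the other date placed the 20:00 samples of 8 July 3.2 h (DAT35) and 2.8 h (DAT21) ahead of their labels. Those of 31 July stood at -0.9 h in both series, and the 22:00 samples of 31 July, set against the profile of 8 July, at -2.4 h (DAT58) and -2.5 h (DAT44), but at 00:00 the 2 series parted (0.7 h and -3.1 h). On 8 July the samples of 20:00, 22:00 and 00:00 were placed close together. They fell at 23.2, 23.1 and 23.1 h in DAT35 and at 22.8, 23.3 and 23.3 h in DAT21. The 00:00 samples of 8 July thus stood behind their labels (-0.9 h and -0.7 h). Slide is argued against, as the displacement at 20:00 exceeded that at 18:00 on the same slide by 3.4 h or more, and so is a swap with the 22:00 samples, which were placed at 23.1 h or later. Later sampling than labelled cannot be told apart from a faster evening in the leaves, such as after an earlier or darker dusk, which was not tested: all 4 groups of probes by peak time placed the sample of DAT35 ahead by 3.1 h or more, but in DAT21 1 group did so by only 1.4 h. Without the 20:00 samples, 1 of the alternatives added later, 8750 probes differed in rhythm, 8001 of them also called with these samples.

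The change from the first to the second 08:00 differed between dates in 13770 probes by the test of that difference. Among the 35 ways to split the 8 samples at 08:00 in equal parts, 9 called at least the 5372 probes of the average change over the 4 series, the real split included, and the highest other called 19253, so chance is not excluded for that average. Of the 8 splits that part the mornings of every series, too few for a share under 0.05, the highest other called 11823.

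A day with other weather on 8 July than on 9 July is a candidate explanation for the change from 8 July, untested here. Sampling at another time than labelled is argued against as the whole of the change. The change from 06:00 to 10:00 on 31 July accounted for at most an r squared of 0.068 over probes. An offset as a part of the change stays open. Set against the profile of 31 July, the first 08:00 samples stood 1.2 h (DAT35) and 0.8 h (DAT21) ahead of their labels, those of the second morning 0.2 h and 0.3 h. The DAT21 sample of the second morning alone is argued against, since the changes of DAT35 and DAT21 correlated at 0.549 over probes. Slide stays open: samples of 1 morning on different slides correlated at 0.275 or more, and the 3 pairs that share a slide and not a morning at -0.25 and -0.262 (each with a sample of the 8 July series) and at 0.276 (31 July only), so the 2 kinds of pairs overlap. Within a slide no series had both mornings.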

How the results depend on the processing

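The alternatives that leave out the sample scanned on another day, the samples of slide 1, the 3 DAT21 samples least like the others, the 20:00 samples or the 08:00 and 20:00 samples, and the one that keeps 1 probe per overlapping group, were chosen after the data were seen. The count of rhythmic probes stayed within 1.5 times of its value in 17 of 18 alternatives (56648 with 1 probe per group of overlapping probes, where fewer probes were tested), and the counts for the sampling date in 14 of 17. Of 322 values of named probes under alternatives, 289 kept their side of the threshold, 33 were no longer past it and 0 turned direction. The values for the rhythm and the rhythm differences have no sign and could not turn. All these probes were chosen for large changes or small p in the same data. Counts at 2-fold or more moved with the background correction and the filter: after normexp 989 probes were higher and 1775 lower on 31 July, and 143 and 76 after later transplanting, with normexp, loess and Aquantile 966 and 1795, and 145 and 80, and among probes well above background in all 51 channels 973 and 1752, and 117 and 49, against 3120 and 4024, and 629 and 244, in the main fit. A fixed slide block gave 2470 and 2470, and 451 and 680. No scaling moved the median change of all probes by more than 0.1 on the log2 scale. Where no construction is named, the cause was not tested.

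With slide as a fixed block, which takes up most of the contrast between series, 5064 probes were higher and 3229 lower on 31 July, 1052 higher and 2204 lower after later transplanting, 1172 had an interaction, 4730 differed in rhythm between dates, and 6 were higher and 58 lower on the second morning. With slide as a random block the counts were 3260 and 4256 for transplanting, 5745 for the interaction, 1065 higher on the second morning, and 1 for rhythm by transplanting. Without the array block 85 were higher and 388 lower on the second morning, 22413 differed in rhythm between dates and 7 between transplantings. Without the replicate block of clock hour, which leaves the daily cycle in the spread, 9943 were higher and 7144 lower on 31 July, 609 and 1030 for transplanting, and 2486 had an interaction, while the calls of the probes named for these 3 comparisons stayed. Without the dye term 787 were higher and 2080 lower on the second morning, and with no filter on dim probes 2487 were lower. With only the 8 samples at 08:00 it was 0 and 0 in limma (19919 at an unadjusted p under 0.05). With 24 h and 12 h harmonics 21167 differed in rhythm between dates and 1 between transplantings, and with probes well above background in all 51 channels 1 differed between transplantings.

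Without the 4 samples of slide 1 the second morning had 22 higher and 85 lower. Without the 3 DAT21 samples least like the others it had 0 and 0 (7273 at an unadjusted p under 0.05), 4238 were lower after later transplanting and 1 differed in rhythm between transplantings. With 1 probe per group 19676 were higher and 14022 lower on 31 July, 3218 higher after later transplanting, 887 higher and 2016 lower on the second morning, 6925 differed in rhythm between dates and 1 between transplantings. Without the 08:00 and 20:00 samples 3464 were higher and 4033 lower after later transplanting, and 14103 had an interaction. Leaving out 1 series at a time gave 0 to 5109 higher and 0 to 9490 lower on the second morning, the 0 without DAT21 and without DAT35. Scaled to the 75th percentile, 42.7% of the probes called on the second morning were higher, against 30.2%, 54.3% of those called for transplanting, against 43.7%, and 50.5% of those called for the sampling date, against 57.8%. Probes not well above background carry only bounds, so signal over background limits the size of the largest changes.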

Other observations

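The levels that stepped by at least 2-fold between every pair of neighbouring series mostly followed the days after transplanting. Among the 95750 probes tested there were 53 such probes. Of these, 40 (75.5%) fell and 9 (17%) rose in the order of days after transplanting, from DAT21 over DAT35 and DAT44 to DAT58, out of 24 possible orders. The other 4 probes spread over 3 orders. This was looked at after the data were seen, probes can share a transcript, and the 24 orders are no measure of chance. Over all tested probes the transplanting differences of the 2 dates correlated at -0.038.

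Overlapping probes gave a view of the strands. Of 37929 pairs of probes that share at least 25 bases on the same strand and were both rhythmic by 2-fold or more, 97.8% peaked within 2 h of each other. Of the 64314 same-strand pairs with both probes called for the date, 99.8% went in 1 direction. Among 386 pairs that lie on opposite strands, 39.4% peaked within 2 h of each other, where 1000 shuffles of the partners gave 12.4% to 25.1%. For the date, 50.6% of the opposite-strand pairs called on both sides went in 1 direction, and 54.1% with the partners shuffled.

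The contrast of morning and evening probes seen between dates also appeared within 8 July. Both comparisons hold the DAT21 samples, with opposite signs, so a deviation of DAT21 alone would give this contrast in each. Of the rhythmic probes with a change of at least 2-fold, 28.4% of those peaking from 06:00 to 08:00 were higher and 8.23% lower in DAT21 than in DAT35, while from 18:00 to 20:00 5.93% were higher and 25.7% lower. The shift of the peak between dates was computed by peak class, with no test between classes: probes of 4-fold or more peaking from 04:00 to 06:00 shifted by 0.961 h (jackknife SE 0.374), those from 16:00 to 18:00 by 0.743 h (0.359), and those from 20:00 to 22:00 by -0.399 h (0.251).

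The splits for the pairs of series and for the rhythm by transplanting were chosen only after the results were seen. Chance assignment of clock times can be excluded for the rhythm, within 100 assignments (87310 probes, at most 0 with clock times shuffled within series). The real assignment was also the 1 highest for the sampling date fitted without transplanting (50190 against at most 1). It was the highest too for the transplanting date fitted beside the sampling date, without the interaction (7773 against at most 274). It was so too for DAT58 against DAT35 (28388 against at most 9603) and for DAT44 against DAT21 (53329 against at most 44860). Between series such assignments cannot exclude chance, since an offset of a whole series largely cancels in them. For the rhythm by transplanting the real assignment gave 0 probes, so the assignments could decide nothing. The 4 series can be split into pairs in only 3 ways, by date (52690 probes), by transplanting (12333) and across both (22562). So few ways allow no share under 0.05, and the split by transplanting called fewer than that across both.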
